A study of Mus musculus with 23 samples.

How the data were processed

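The deposited file held counts per gene for 23 libraries of total RNA from pulverised mouse cortex, prepared with ribosomal RNA depletion per the labels. The counts were deposited as unnormalised reads or fragments per Ensembl gene. The submitters' processing notes list Trimmomatic 0.32, STAR 2.3.0e, bedtools 2.27.1 and featureCounts 1.4.4 with the mm10 assembly and do not state what the authors did with each to make the counts. The annotation release and the strand setting of the counting are not given in the sources used here. The values were whole numbers with no sign of normalisation. Of 39017 genes, 37607 had an identifier in the GENCODE M21 annotation of GRCm38, from which symbols, biotypes and coordinates were taken, and 1410 did not.

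Groups followed the genotype, age and replicate labels. Replicates were separate animals with their own numbers in the titles, and the 2 libraries of animal 2498 (WT replicate 3 at 10 weeks) were summed, which leaves 22 animals. Sex labels matched the expression of Xist and of Y-linked genes in 22 of 22 animals. For G34W replicate 2 the title begins with M, as in males, while its sex label is female, as its expression of these genes also was. Total counts ranged from 28.4 to 90.1 M (M, mega) per library.

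Differential expression was tested with edgeR 4.0.16 (quasi-likelihood, robust), after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit of the 14 animals at 10 weeks covered the 3 comparisons with WT and those between substitutions (21282 genes, 10 residual degrees of freedom, common biological coefficient of variation 0.137). A fit of the 8 animals at day 7 had sex as a covariate (20455 genes, 5 degrees of freedom, 0.124). A fit of all 22 animals gave the difference of the G34R effects between ages and the age comparison in WT (22425 genes, 16 degrees of freedom, 0.133). Sex-specific genes were removed before testing. The SE of a log2 fold change was its size divided by the square root of the quasi-likelihood F. CPM printed per group are on 1 TMM scale over all 22 animals.

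Gene lists were written from general knowledge before the data were examined, 45 lists with 851 genes, covering glial, neuronal and vascular cell types, neighbouring brain regions, immune and metabolic pathways, development and chromatin. The 44 lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data. List results between substitutions and between ages were added to the planned ones. After list results had been seen, 1 wrong symbol match was removed from each of 3 lists.

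The groups, the comparisons, the alternatives and a rule for named genes were fixed before the data were examined. The rule took H3f3a, the genes with the largest change (up to 10 per direction against WT and 5 in the other comparisons) among those past the threshold with at least 1 CPM in a compared group and, for pairs of groups, ranges that do not overlap, and up to 3 members of each list with the smallest adjusted p. The text names part of this set. Named after their values were seen were Dmrt3, Sox3, C4b, Phyh, Pi15, Il34, Tet1 and Kdm2b for G34R at 10 weeks, Rpl26, AA465934, Ndn, Minar2, Tet1 and Kdm2b for G34V, and Minar2 and Hrasls for G34W. Some genes that the rule selects are not reported here.

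Shared calls between substitutions were compared with the number expected of independent lists, with 20 simulations of unchanged groups against the same WT animals, and with WT animals split into 2 sets of 3. Simulated data with 200 changed genes tested the power, in 1 run per comparison. The changed genes were drawn from those with a mean of at least 1 CPM, so the power does not cover genes below that level. No batch differences were simulated. Of genes changed 2-fold, 89.6% were recovered for G34R, 86.6% for G34V and 82.1% for G34W at 10 weeks, 92.5% at day 7 and 77.6% for the difference between ages. Of genes changed 1.5-fold, 64.2%, 64.2%, 62.7%, 64.2% and 35.8% were recovered. The share of false calls was 9.2%, 6.7%, 4.7%, 9.6% and 4.1%, against a nominal 5%.

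Alternatives were RLE scaling, no filter, a CPM filter, mitochondrial and rRNA genes left out, sex genes kept, DESeq2 1.42.0, limma-voom with quality weights, an estimated correlation, the libraries of animal 2498 kept apart, only the compared groups, runs of consecutive animal numbers as a block, the sex label as a covariate, no sex covariate at day 7, only males for age, only the WT and G34R groups for the difference between ages, and each animal left out. The labels give no batch. Blocking on 2 library sets split by the share of mitochondrial protein-coding counts, and use of only the set that holds a mutant, were chosen after seeing the data. Both used libraries rather than animals, so in the block the 2 libraries of animal 2498, 1 in each set, counted as separate samples. The analysis used R 4.3.3 and Python 3.11.15. Raw reads, allele-specific expression and DNA methylation were not analysed here.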

Results

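Total RNA from the cortex of 22 mice was sequenced after depletion of ribosomal RNA. The mice were wild type (WT) or carried 1 of 3 substitutions of glycine 34 of the histone variant encoded by H3f3a, to arginine (G34R), valine (G34V) or tryptophan (G34W), each heterozygous per the labels. At 10 weeks there were 6 WT, 3 G34R, 3 G34V and 2 G34W animals, and at postnatal day 7 there were 4 WT and 4 G34R animals. The series asks what a single change at this residue does to the brain, with recruitment of the DNA methyltransferase DNMT3A and a progressive loss of neurons as its stated subjects. Total counts per library ranged from 32.3 to 90.1 M (M, mega) at 10 weeks and from 28.4 to 53.5 M at day 7. All 10-week animals were labelled male except G34W replicate 2, and each day-7 genotype held 2 males and 2 females.

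H3f3a, the edited gene (GRCm38 chromosome 1, 180800832 to 180813943, minus strand) was measured first. Its level was 45.2 ± 3.89 CPM (mean ± SD, n = 6) in WT at 10 weeks, 43.1 ± 1.98 (n = 3) in G34R, 41.5 ± 1.86 (n = 3) in G34V and 42.0 ± 5.1 (n = 2) in G34W. The log2 fold changes of -0.07, -0.12 and -0.11 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.688, 0.464 and 0.541). At day 7, H3f3a was lower in G34R, at 60.7 ± 1.66 CPM (n = 4) against 72.5 ± 3.03 (n = 4), a log2 fold change of -0.25 (SE 0.0416, edgeR adjusted p = 0.0429). That call ended when any 1 of the 8 day-7 animals was left out, with edgeR adjusted p from 0.0949 to 0.211. Counts per gene do not show the substituted codon, so these levels are no check of the genotype labels.

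The first comparison asked how the cortex of G34R mice differed from WT at 10 weeks. Genes of activated microglia, reactive astrocytes, lysosomes, complement and the interferon response rose in G34R, and genes of cholesterol synthesis fell. Gfap (chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose from 128 ± 12.3 CPM (n = 6) to 451 ± 17.4 CPM (n = 3), a log2 fold change of 1.82 (SE 0.0723, edgeR adjusted p = 7.53e-11). Cst7 (chromosome 2, 150570415 to 150578944), which encodes the cysteine protease inhibitor cystatin F, rose from 0.0418 ± 0.0362 CPM, close to the detection limit, to 4.43 ± 0.62 CPM, a log2 fold change of 6.65 (SE 0.347, edgeR adjusted p = 3.22e-09). In all, 626 genes were higher and 564 lower in G34R among 21282 tested at an adjusted p under 0.05, and 327 of these 1190 changed at least 2-fold.

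Among 22 genes of disease-associated microglia, 16 rose and 0 fell (16 adjusted over the list alone). Besides Cst7 they included Itgax, which encodes the integrin CD11c, with a log2 fold change of 4.45 (SE 0.275), the beta-glucan receptor gene Clec7a (4.52, SE 0.346) and the chemokine genes Ccl3 (4.18, SE 0.425) and Ccl4 (4.65, SE 0.629). Cd68, a lysosomal glycoprotein gene of macrophages and microglia, rose by 1.75 (SE 0.0944), from 5.02 ± 0.306 to 16.8 ± 1.25 CPM. Of 14 homeostatic microglial genes 10 rose and 0 fell (11 adjusted over the list alone), by at most 0.828 on the log2 scale. Among them were the fractalkine receptor gene Cx3cr1 (0.67, SE 0.077) and the colony-stimulating factor receptor gene Csf1r (0.53, SE 0.0569). Phagocytosis and lysosomal genes rose nearly throughout, 19 of 21 tested (19 adjusted over the list alone), led by cathepsin S (Ctss, 1.4, SE 0.0856), lysozyme (Lyz2, 2.12, SE 0.132) and Laptm5 (0.86, SE 0.0647). Of 19 complement genes 11 rose and 0 fell (12 adjusted over the list alone), with C1qc at 1.25 (SE 0.0957) and C3 at 2.92 (SE 0.282).

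Reactive astrocyte genes rose in 12 of 23 cases (15 adjusted over the list alone), including the serine protease inhibitor gene Serpina3n (1.30, SE 0.109) and Ggta1 (1.09, SE 0.137) beside Gfap. Of 25 interferon response genes 21 rose and 0 fell (23 adjusted over the list alone), with a median log2 fold change of 1.49. They included Trim30a (1.60, SE 0.19), the transcription factor gene Irf9 (1.14, SE 0.142) and Lgals3bp (1.49, SE 0.157). Of 15 cytokine and chemokine genes 10 rose and 0 fell (11 adjusted over the list alone), among them Tlr2, a receptor for bacterial lipoproteins (2.15, SE 0.186), Cxcl16 (1.87, SE 0.169) and Cxcl10, an interferon-induced chemokine (3.25, SE 0.45). Of 18 cholesterol synthesis genes 11 fell and 0 rose (16 adjusted over the list alone), including Hmgcs1 (-0.43, SE 0.0769) and Cyp51 (-0.41, SE 0.069). All 8 lists named so far passed camera with a preset and with an estimated correlation. The camera adjusted p with an estimated correlation was 0.000112 for disease-associated microglia, 0.0088 for homeostatic microglia, 0.000828 for phagocytosis, 0.000851 for complement, 0.00301 for reactive astrocytes, 0.018 for interferon response, 0.000112 for cytokines and 0.018 for cholesterol synthesis.

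Of 15 genes of class I antigen presentation 8 rose and 1 fell (11 and 1 adjusted over the list alone). The beta-2-microglobulin gene B2m rose by 0.92 (SE 0.0984) and the immunoproteasome subunit gene Psmb8 by 1.24 (SE 0.178), whereas Psmb10, another immunoproteasome subunit gene, fell to 19.1 ± 1.25 CPM from 27.7 ± 3.03 (-0.54, SE 0.0936). This list lost its camera call with an estimated correlation (adjusted p = 0.148), as did 8 lists with few called members. Of these, by camera with an estimated correlation, 4 concerned neurons and myelin, namely myelin (1 of 20 lower, 3 adjusted over the list alone, median -0.27, p = 0.734), immediate early genes (0 of 19, median -0.55, p = 0.734), deep-layer excitatory neurons (2 of 18 lower, 7 adjusted over the list alone, p = 0.3) and ion channels (1 of 20 lower, p = 0.746). With an estimated correlation the camera adjusted p was 0.734 for mitochondrially encoded genes (0 of 13, 6 lower adjusted over the list alone), 0.691 for cell cycle (1 of 20 higher, 3 adjusted over the list alone), and 0.746 for nuclear genes of oxidative phosphorylation (2 of 26 lower) and for striatal markers (0 of 14, median -0.33). The remaining 27 of 44 lists, among them interneurons, upper-layer excitatory neurons, synaptic genes, ribosomal proteins and chromatin regulators, did not pass.

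The largest decreases with clear expression in WT were outside the lists. Minar2 (chromosome 18, 59062248 to 59076962) fell from 16.4 ± 0.628 to 3.34 ± 0.203 CPM, a log2 fold change of -2.29 (SE 0.0931, edgeR adjusted p = 7.53e-11). The phospholipase-like gene Hrasls changed by -2.09 (SE 0.161), Dkkl1 by -2.05 (SE 0.214) and the zinc finger gene Zfp648 by -2.71 (SE 0.417), all lower. Among developmental genes, the imprinted gene Ndn fell from 109.7 ± 12.5 to 58.7 ± 6.36 CPM (-0.90, SE 0.106). The proneural factor gene Neurog2 rose at a low level, from 0.339 ± 0.106 to 1.01 ± 0.469 CPM (1.58, SE 0.328, edgeR adjusted p = 0.00621, or 0.0757 without G34R replicate 2). Fezf2, which specifies deep-layer projection neurons, fell by 0.58 on the log2 scale (SE 0.124, edgeR adjusted p = 0.00793, or 0.0601 without G34R replicate 2).

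The count of 1190 genes was 692 without G34R replicate 1, 758 without replicate 2 and 755 without replicate 3, and 751 with runs of consecutive animal numbers as a block, of which 629 were among the 1190. The G34R libraries shared their low share of mitochondrial protein-coding counts (0.89% to 1.03%) with 3 WT libraries and with no G34V or G34W library (1.12% to 1.36%). Within that set of 6 libraries the comparison called 965 genes.

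**Figure D1:**
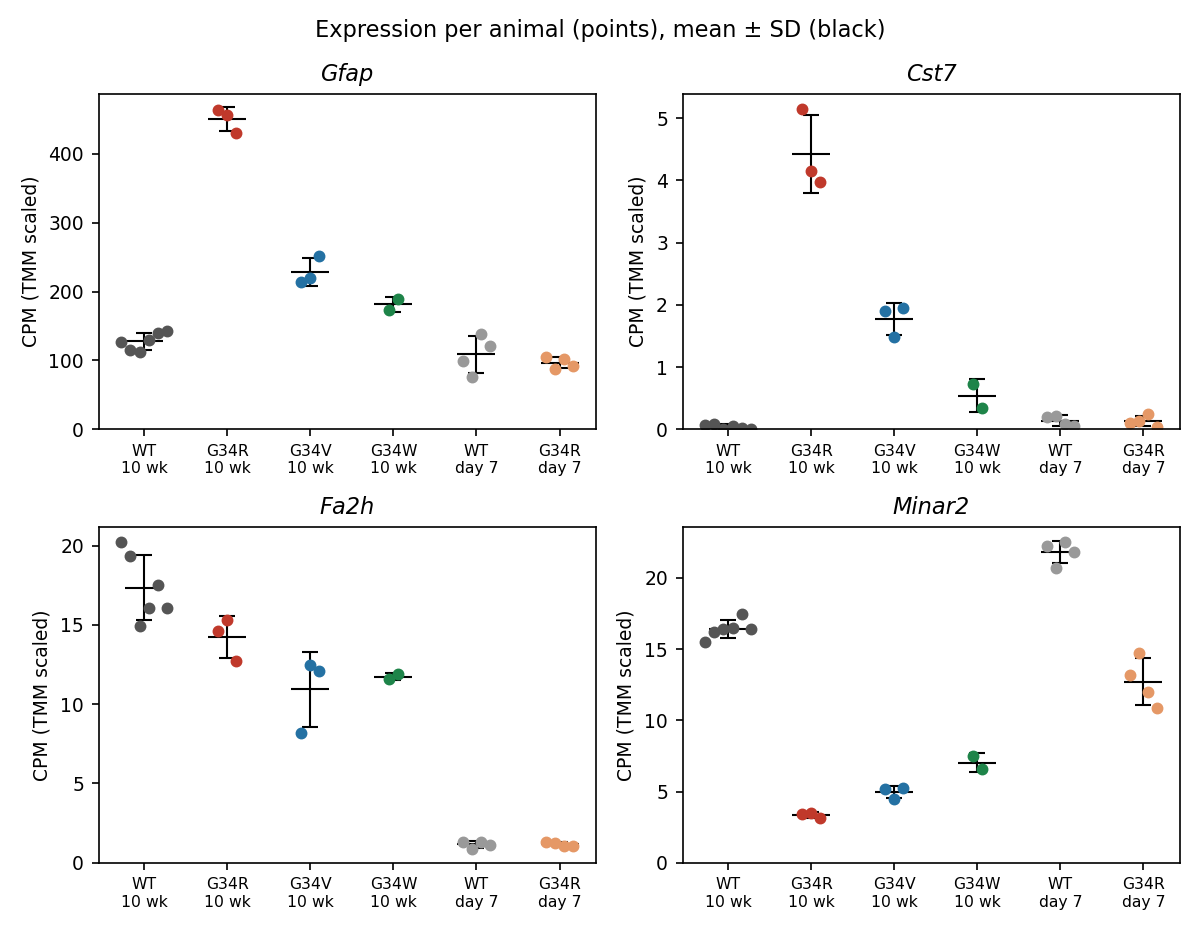
Expression of Gfap, Cst7, Fa2h and Minar2 in each of the 22 animals, in TMM-scaled CPM on linear axes from 0, with 1 point per animal and black bars for the group mean ± SD. At 10 weeks Gfap lay at 451 ± 17.4 CPM in G34R against 128 ± 12.3 in WT, with G34V and G34W between them, and Minar2 was below WT in all 3 mutants.

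The second comparison asked the same of G34V at 10 weeks. Genes of disease-associated microglia, phagocytosis, complement and cytokines rose in G34V as well, and 8 of 20 myelin genes fell, in a list that did not pass with an estimated correlation (camera adjusted p = 0.153). Cst7 rose to 1.77 ± 0.254 CPM (n = 3; log2 fold change 5.33, SE 0.365, edgeR adjusted p = 1.64e-07) and Gfap to 229 ± 19.9 CPM (0.84, SE 0.0733, edgeR adjusted p = 2.17e-06). In all 335 genes were higher and 570 lower, 905 together, and 213 of them changed at least 2-fold.

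Of 21 phagocytosis genes 12 rose and 0 fell (15 adjusted over the list alone), including Lyz2 (1.31, SE 0.135) and Ctss (0.81, SE 0.0869). Of 22 disease-associated microglial genes 10 rose and 1 fell (11 and 2 adjusted over the list alone), among them Clec7a (3.03, SE 0.36), Itgax (2.97, SE 0.289) and Cd68 (1.02, SE 0.097). Of 19 complement genes 9 rose and 0 fell (11 adjusted over the list alone), with C3 at 1.97 (SE 0.293) and C4b, whose reads are hard to tell from those of its near-identical copy C4a, at 1.66 (SE 0.17). Of 15 cytokine genes 4 rose (6 adjusted over the list alone), Tlr2 among them (1.52, SE 0.192). These 4 lists also passed camera with an estimated correlation (adjusted p = 0.0488 for phagocytosis, 0.0116 for disease-associated microglia, 0.0293 for complement and 0.0116 for cytokines).

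Of 20 myelin and mature oligodendrocyte genes 8 fell and 0 rose (17 adjusted over the list alone), with a median log2 fold change of -0.54. They included Fa2h, which makes the 2-hydroxylated lipids of myelin (-0.66, SE 0.127). The adjusted p of this list was 7.66e-20 with the preset correlation and 0.153 with an estimated correlation. Of 13 oligodendrocyte precursor genes 2 fell (4 adjusted over the list alone), including the lineage factor gene Olig1 (-0.39, SE 0.0734), and the adjusted p was 0.24 with an estimated correlation. Of 25 interferon response genes 5 rose (18 adjusted over the list alone, median 0.79, adjusted p = 0.307 with an estimated correlation), among them Lgals3bp (0.87, SE 0.161). Homeostatic microglia (5 of 14 higher, 7 adjusted over the list alone, camera adjusted p = 0.153 with an estimated correlation), reactive astrocytes (5 of 23 higher, 7, p = 0.168) and cholesterol synthesis (4 of 18 lower, 10, p = 0.147) also lost their calls. Olfml3 (0.69, SE 0.114) was among the homeostatic microglial genes that rose, and Rgs16 (-1.12, SE 0.202) among 2 of 10 thalamic markers that fell (camera adjusted p = 0.677). By camera with an estimated correlation the call was also lost for deep-layer neurons (1 of 18 lower, 4 adjusted over the list alone, p = 0.321), immediate early genes (1 of 19 lower, p = 0.816), class I antigen presentation (1 of 15 higher and 1 lower, p = 0.816) and oxidative phosphorylation (0 of 26, p = 0.816).

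The endoplasmic reticulum chaperone gene Hspa5 rose from 222.5 ± 6.79 to 301.5 ± 39.5 CPM (0.44, SE 0.0685) and Xbp1, a transcription factor gene of the unfolded protein response, from 64.8 ± 4.15 to 83.7 ± 6.62 CPM (0.37, SE 0.0672). Their stress list, with 6 of 18 genes higher and 2 lower, did not pass camera (adjusted p = 0.0598). Lamp5, a marker of upper-layer neurons and of a class of interneurons, fell from 111 ± 11.7 to 69.5 ± 4.75 CPM (-0.68, SE 0.0778). Genes outside the lists changed too. Rec8, a meiotic cohesin gene, changed by -2.79 (SE 0.327), Egfl6 by -2.74 (SE 0.236), Hrasls by -2.36 (SE 0.165) and the zinc finger gene Casz1 by -1.89 (SE 0.184), all lower. Gpr179, a gene of retinal bipolar cells on chromosome 11, was at 8.02 ± 0.449 CPM against 0.519 ± 0.181 (3.96, SE 0.226), but it also varied within the day-7 genotypes, from 0.65 to 3.65 CPM in WT and from 0.87 to 17.27 in G34R. The transcription factor genes Dmrt3 (2.47, SE 0.327) and Sox3 (1.79, SE 0.185) rose from low levels.

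The count of 905 genes was 497 without G34V replicate 1, 513 without replicate 2, and 340 with number runs as a block, where 320 were among the 905. With that block the calls of Fa2h (edgeR adjusted p = 0.0766) and Olig1 (0.0632) ended. Within the 9 libraries of higher mitochondrial share, which hold the G34V animals, 519 genes were called and Lgals3bp no longer passed (edgeR adjusted p = 0.0538).

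The third comparison, of G34W with WT at 10 weeks, rested on 2 G34W animals. A few microglial genes were higher, with 4 of 22 disease-associated genes past the threshold, and 4 of 20 myelin genes were lower. Cst7 rose to 0.537 ± 0.267 CPM (n = 2; log2 fold change 3.56, SE 0.496, edgeR adjusted p = 0.00206) and Gfap to 181 ± 10.9 CPM (0.51, SE 0.0848, edgeR adjusted p = 0.00696). In all 120 genes were higher and 227 lower, 347 together, and 74 changed at least 2-fold. No list kept its camera call with an estimated correlation.

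Of 20 myelin genes 4 fell and 0 rose (12 adjusted over the list alone, median -0.44), with the cytoskeletal gene Ermn (-0.68, SE 0.137) among them, and the adjusted p was 5.42e-13 with the preset and 0.31 with an estimated correlation. Of 19 immediate early genes 1 fell (4 adjusted over the list alone, median -0.92, adjusted p = 0.394 with an estimated correlation), and that was the neurotrophin gene Bdnf, from 31.2 ± 4.93 to 17.5 ± 4.48 CPM. Of 13 mitochondrially encoded genes 1 rose (6 adjusted over the list alone, median 0.49, p = 0.31 with an estimated correlation), mt-Nd5 (0.86, SE 0.18). Of 22 disease-associated microglial genes 4 rose (8 adjusted over the list alone, camera adjusted p = 0.258 with an estimated correlation), among them Clec7a (2.65, SE 0.423) and Itgax (2.31, SE 0.352). Of 19 complement genes 3 rose (6 and 1 lower adjusted over the list alone, camera adjusted p = 0.255), with C4b at 1.10 (SE 0.197), its copy C4a again not told apart. Lyz2 (1.01, SE 0.158) and the Fc receptor gene Fcgr2b (1.11, SE 0.199) were the 2 of 21 phagocytosis genes that rose (7 adjusted over the list alone, camera adjusted p = 0.575). Tlr2 (1.11, SE 0.229) was among 3 of 15 cytokine genes (camera adjusted p = 0.255). Of 18 cholesterol synthesis genes 1 fell (9 adjusted over the list alone, camera adjusted p = 0.255), and 2 of 22 imprinted genes rose (3, camera adjusted p = 0.289). Pcdhb9 (0.53, SE 0.0898) was the 1 of 23 clustered protocadherins that rose (3 adjusted over the list alone, camera adjusted p = 0.289).

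Markers of neighbouring tissue also differed in this group by the preset camera test alone. Choroid plexus markers had a median log2 fold change of -1.26 with 0 of 12 called (camera adjusted p = 0.552 with an estimated correlation), hippocampal markers -0.67 with 0 of 10 (3 adjusted over the list alone, p = 0.255) and striatal markers 0.32 with 0 of 14 (p = 0.62). Homeostatic microglia (1 of 14 higher, p = 0.552), class I (0 of 15, p = 0.575) and class II (0 of 7, p = 0.552) antigen presentation, interferon response (0 of 25, p = 0.82) and deep-layer neurons (1 of 18 lower, p = 0.587) passed camera with the preset correlation only. Outside the lists, Sowahb fell from 21.3 ± 4.33 to 6.33 ± 1.18 CPM (-1.74, SE 0.228), Col11a2, a fibrillar collagen gene, changed by -1.46 (SE 0.155), Egfl6 by -1.46 (SE 0.252), the serotonin receptor gene Htr5b by -1.89 (SE 0.369) and Lefty1, which has a near copy in Lefty2, by -1.42 (SE 0.289). Dmrt3 (2.63, SE 0.367), Sox3 (1.70, SE 0.214) and Neurog2 (1.81, SE 0.373) rose and Lamp5 fell (-0.61, SE 0.0909).

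The count of 347 genes was 58 without G34W replicate 1, 590 without replicate 2, 219 without WT replicate 1, 15 with number runs as a block (14 of them among the 347) and 91 within the libraries of higher mitochondrial share. One of the 2 G34W animals was female and all WT were male. No other 10-week animal was female, so with the sex label as a covariate the G34W effect rested on G34W replicate 1 alone. That fit is therefore no adjustment for sex, and its count is not given. DESeq2 called 917, voom with quality weights 28, and a fit of only these 2 groups 140. More genes than 15 are named for G34W, so some of their calls ended with number runs as a block. G34W replicate 1 stood apart from the other 10-week libraries, with 18.2% of its counts on signal recognition particle RNA against at most 14.0% and 62.5% on protein-coding genes against at least 72.7%. Without this library the edgeR calls of the genes named so far for G34W other than Gfap, Dmrt3, Sox3 and Col11a2 ended, with adjusted p from 0.0501 (Cst7, Lamp5) to 0.282 (Bdnf). Without G34W replicate 2 the calls of Ermn (edgeR adjusted p = 0.125), C4b (0.0642) and Lefty1 (0.0955) ended, and those of Bdnf and mt-Nd5 ended in 4 and 5 of the 8 cases of 1 animal left out.

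**Figure D2:**
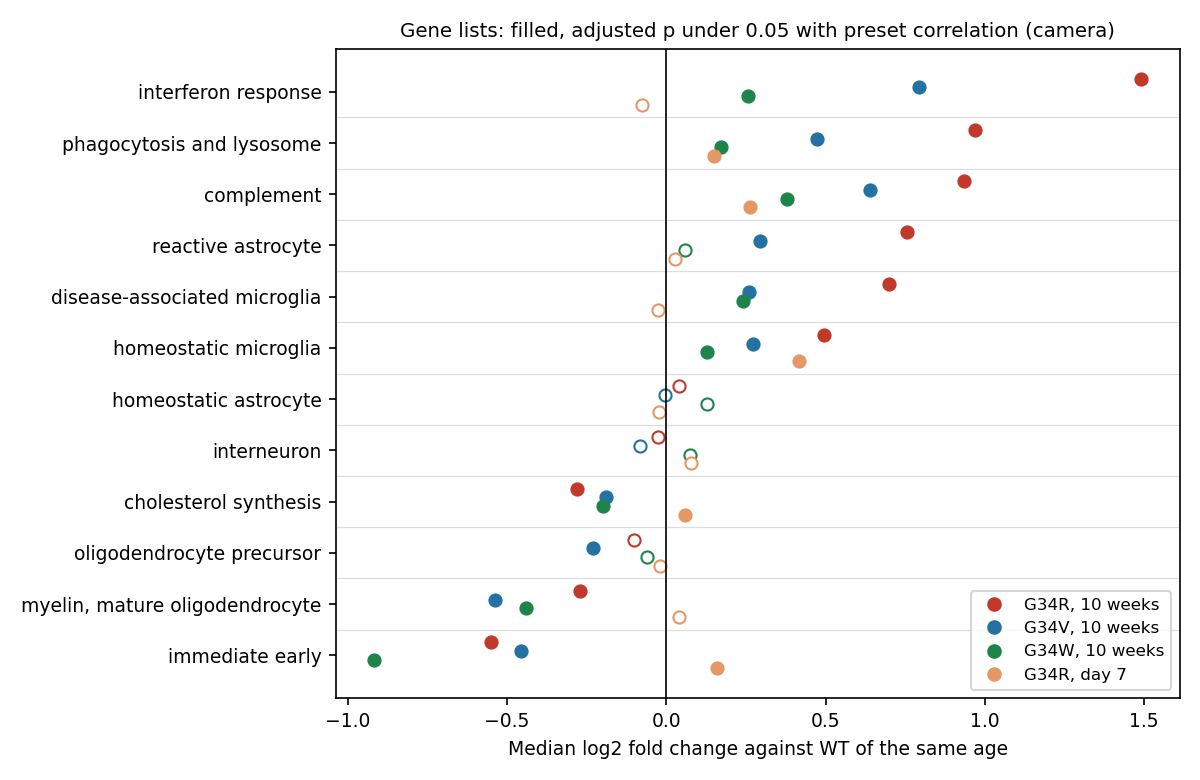
Median log2 fold change against WT of the same age (horizontal axis) of 12 gene lists in G34R, G34V and G34W at 10 weeks and in G34R at day 7, with filled points for lists at an adjusted p under 0.05 in camera with a preset correlation. The interferon response list lay at 1.49 in G34R at 10 weeks and the myelin list at -0.54 in G34V and -0.44 in G34W, where it did not pass with an estimated correlation (camera adjusted p = 0.153 and 0.31).

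The substitutions were then compared with each other at 10 weeks. The G34R libraries share no library set with those of G34V and G34W, so these differences are confounded with library set except through the WT libraries, which lie in both sets. With library set as a block, an alternative chosen after the data were seen, 11 genes instead of 49 differed between G34R and G34V, and 35 instead of 397 between G34R and G34W. Without that block, some astrocytic and microglial genes were higher in G34R than in either of the others. Gfap, which kept its call with the block, was 0.98 higher on the log2 scale in G34R than in G34V (SE 0.0875, edgeR adjusted p = 1.8e-05) and 1.31 higher than in G34W (SE 0.101, edgeR adjusted p = 5.76e-06). Serpina3n was 1.5 higher than in G34W (SE 0.156, edgeR adjusted p = 0.00014). G34R and G34V differed in 49 genes, 37 higher and 12 lower in G34R, of which 9 differed at least 2-fold. Gpnmb, a transmembrane glycoprotein gene of phagocytic cells, was higher in G34R (1.36, SE 0.212, edgeR adjusted p = 0.00971, or 0.0799 without G34V replicate 1), and Rec8 was too (2.66, SE 0.353), as a result of its low value in G34V. In list tests added to the planned ones, 5 of 22 disease-associated microglial genes (15 adjusted over the list alone, camera adjusted p = 0.00234 with an estimated correlation), 5 of 21 phagocytosis genes (17, p = 0.0322), 2 of 23 reactive astrocyte genes (7, p = 0.044) and 1 of 15 cytokine genes (3, p = 0.00684) were higher in G34R than in G34V. List tests between substitutions were not repeated with a block or with an animal left out. The count of 49 was 16, 22 and 25 without G34R replicates 1, 2 and 3, and 13, 18 and 129 without G34V replicates 1, 2 and 3. It was 3 with number runs as a block, and 281 with DESeq2, 183 of them higher, against 37 of 49.

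G34R and G34W differed in 397 genes, 200 higher and 197 lower in G34R, of which 101 differed at least 2-fold. Cst7 was 3.10 higher in G34R (SE 0.41) and Itgax 2.14 (SE 0.362, edgeR adjusted p = 0.00672, or 0.0505 without G34W replicate 2), while Trim71, which encodes an RNA-binding ubiquitin ligase of early development, was lower (-1.59, SE 0.273). In the added list tests 12 of 22 disease-associated microglial genes (16 adjusted over the list alone, camera adjusted p = 0.00229 with an estimated correlation) and 11 of 21 phagocytosis genes (19, p = 0.0152) were higher in G34R. So were, by camera, 5 of 23 reactive astrocyte genes (13 and 1 lower, adjusted p = 0.0191) and 3 of 15 cytokine genes (7, adjusted p = 0.014). These list tests, too, were not repeated with a block or with an animal left out. The count of 397 was 159, 149 and 164 without G34R replicates 1, 2 and 3, 212 without G34W replicate 1, and 6 with number runs as a block. G34V and G34W differed in 32 genes, 8 higher and 24 lower in G34V. No list differed between these 2 with an estimated correlation (lowest p = 0.365). The count of 32 was 10 without G34V replicate 1, 10 without replicate 2, 301 without G34W replicate 2 and 4 with number runs as a block, and with DESeq2 118 of 309 genes were higher in G34V.

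The 3 comparisons with WT shared many calls. G34R and G34V had 196 higher and 310 lower genes in common, where independent lists of these sizes would share 9.9 and 15.1, G34R and G34W had 35 and 104 (3.5 and 6), and G34V and G34W had 37 and 131 (1.9 and 6.1). All 3 comparisons used the same WT animals. At an unadjusted p under 0.01 the pairs shared 335 higher and 487 lower, 128 and 274, and 137 and 345 genes, against at most 14 and 13, 12 and 11, and 10 and 8 in 20 simulations of unchanged groups against those animals. The covariance of the log2 fold changes across 16810 genes was 0.0448, 0.0249 and 0.0404 for these pairs, against simulated means of 0.00894, 0.00887 and 0.00889. The correlation was 0.585, 0.284 and 0.507 against simulated means of 0.326, 0.269 and 0.27. For G34R and G34W the correlation was thus close to its simulated mean, while the covariance lay above the highest simulated value of 0.0102. A correlation is divided by the spread of the fold changes, which true differences enlarge, so it compares less directly with unchanged groups. The WT animals were also split into 2 sets of 3, each used for 1 of the 2 comparisons, over 20 splits. The mean numbers shared were then 101.8 higher and 191.7 lower, 16.1 and 49.2, and 17.1 and 59.6, with covariances of 0.034, 0.013 and 0.0287. Neither the simulations nor the splits model library sets or number runs. All G34V and G34W libraries lie in the set of higher mitochondrial share, so calls shared through that set are not excluded. In all 3 substitutions 25 genes were higher, among them Gfap, Cst7, Cd68, Itgax, Clec7a, Lyz2, Tlr2, Fcgr2b, Dmrt3 and Sox3, and 91 were lower, among them Minar2, Hrasls, Col11a2, Casz1, Sowahb and Lamp5. These sets rest on the G34W calls, of which 38 of 347 remained without G34W replicate 1. Without it the G34W calls of Cst7, Itgax, Clec7a, Lyz2, Tlr2, Fcgr2b, Sowahb and Lamp5 ended, and those of Gfap, Dmrt3, Sox3, Minar2, Hrasls and Col11a2 held. Minar2 was at -2.29, -1.72 and -1.22 in G34R, G34V and G34W, and Dmrt3 at 2.16, 2.47 and 2.63.

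At postnatal day 7 the question was which differences G34R mice already carried. Only homeostatic microglial genes, among the lists, were higher in G34R with an estimated correlation, and single genes changed at least 2-fold. Pi15, a secreted protease inhibitor gene (chromosome 1, 17601901 to 17630939), was higher in G34R at 5.46 ± 0.521 CPM (n = 4) against 1.59 ± 0.383 (n = 4), a log2 fold change of 1.79 (SE 0.171, edgeR adjusted p = 0.00392). Il34, a ligand of the receptor CSF1R on microglia (chromosome 8, 110741829 to 110805924), was at 21.4 ± 1.06 against 12 ± 1.5 CPM (0.85, SE 0.0833, edgeR adjusted p = 0.00392). Phyh, a peroxisomal enzyme gene of branched fatty acid oxidation (chromosome 2, 4919019 to 4938730), was lower at 17.8 ± 0.76 against 35.3 ± 1.67 CPM (-0.99, SE 0.055, edgeR adjusted p = 5.37e-05).

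Of 20455 genes tested 23 were higher and 40 lower at day 7, and 12 of these 63 differed at least 2-fold. Of 14 homeostatic microglial genes 3 rose (10 adjusted over the list alone, median 0.42, camera adjusted p = 0.0343 with an estimated correlation), namely Cx3cr1 (0.45, SE 0.0632), Fcrls (0.53, SE 0.079) and the purine receptor gene P2ry12 (0.57, SE 0.0969). Laptm5 (0.56, SE 0.0873) was the 1 of 21 phagocytosis genes (6 adjusted over the list alone, p = 0.692 with an estimated correlation), Itgam (0.71, SE 0.12) the 1 of 19 complement genes (5 and 1 lower, p = 0.36) and Casp1 (0.97, SE 0.155) the 1 of 12 cytokine genes (3 and 1 lower, p = 0.308), all by camera. The other lists past the preset camera test had no called member. With an estimated correlation camera gave p = 0.356 for clustered protocadherins (0 of 23, 4 adjusted over the list alone), 0.692 for immediate early genes, 0.408 for hippocampal and for olfactory bulb markers, and 0.871 for mitochondrially encoded genes, cell cycle and cholesterol synthesis (median 0.06). The neuropeptide gene Gal (1.61, SE 0.252), the serotonin receptor gene Htr3a (0.88, SE 0.153) and Pnmt, which encodes the enzyme that makes adrenaline (2.07, SE 0.28), were also higher. Minar2 (-0.78, SE 0.0857), the tyrosine breakdown gene Fah (-1.05, SE 0.119), the receptor genes S1pr5 (-1.42, SE 0.246) and Ror2 (-0.83, SE 0.139), Mxra7 (-1.03, SE 0.167) and Psmb10 (-0.41, SE 0.0641) were lower.

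The day-7 count depended on single animals. It was 31, 19, 39 and 7 without G34R replicates 1 to 4 and 7, 28, 39 and 5 without WT replicates 1 to 4. Only Pi15, Il34 and Phyh of the genes named here passed without any 1 animal. Minar2 failed only without WT replicate 4 (edgeR adjusted p = 0.0575) and Fah without WT replicate 4 (0.0575) or G34R replicate 4 (0.0635). The other named genes failed in 5 to 8 of the 8 cases. DESeq2 called 211 genes, 104 higher and 107 lower, and without a filter on low counts edgeR called 159.

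**Figure D3:**
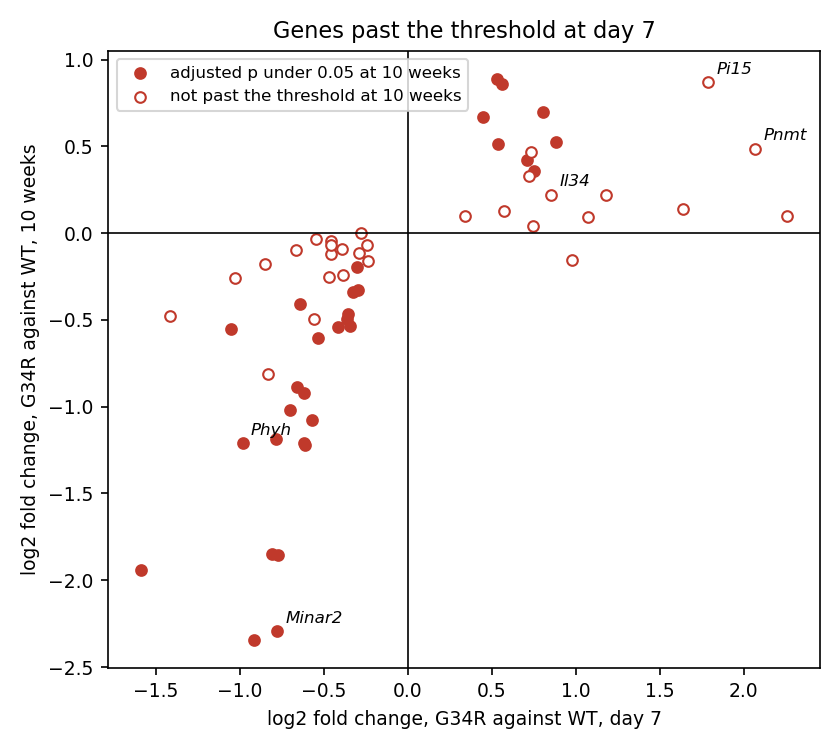
Log2 fold change of G34R against WT at day 7 (horizontal axis) and at 10 weeks (vertical axis) for the 61 genes called at day 7 and tested at both ages, with filled points for genes also called at 10 weeks. Of these genes 60 had the same sign at both ages, and Minar2 was lower at both.

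The difference between the G34R effects at the 2 ages was tested in a model of all 22 animals. The glial response of 10 weeks was larger than at day 7. Cst7 had an effect 6.75 larger on the log2 scale at 10 weeks (SE 0.735, edgeR adjusted p = 1.48e-05), Itgax 4.58 (SE 0.499), Clec7a 4.30 (SE 0.616), Lyz2 2.55 (SE 0.276), Cxcl16 2.43 (SE 0.235) and Gfap 1.99 (SE 0.179, edgeR adjusted p = 6.87e-06). Of 22425 genes 126 had an effect that was higher and 135 an effect that was lower at 10 weeks, 261 together, and 103 of these by at least 2-fold.

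By list, the effect was higher at 10 weeks in 11 of 22 disease-associated microglial genes (14 adjusted over the list alone, camera adjusted p = 9.84e-05 with an estimated correlation), 8 of 25 interferon response genes (21, p = 0.00658) and 10 of 21 phagocytosis genes (18, p = 0.00482). By the same camera test it was higher in 6 of 19 complement genes (9, adjusted p = 0.00658), 6 of 23 reactive astrocyte genes (10, adjusted p = 0.0082) and 3 of 16 cytokine genes (5 and 1 lower, adjusted p = 0.000347). It was lower in 6 of 18 cholesterol synthesis genes (13, camera adjusted p = 0.00658), among them the lanosterol synthase gene Lss (-0.36, SE 0.0682) and the squalene synthase gene Fdft1 (-0.35, SE 0.0763). Members with a higher effect included the interferon response gene Usp18 (2.61, SE 0.533), C1qa (0.98, SE 0.166) and Ggta1 (1.19, SE 0.187). Class I antigen presentation lost its call with an estimated correlation (3 of 15, p = 0.128), as did 10 lists in which at most 1 member was called (p from 0.212 to 0.763). Outside the lists that passed, Zfp648 (-3.22, SE 0.475), Trim71 (-2.41, SE 0.492), Lamp5 (-0.96, SE 0.155) and Ndn (-0.80, SE 0.139) had a lower effect at 10 weeks. The count of 261 was 133 without G34R replicate 1 and 172 without replicate 2 of the 10-week animals, and 460 with DESeq2. The calls of Fdft1 and Usp18 ended without G34R replicate 1 at 10 weeks (edgeR adjusted p = 0.0657 and 0.0531), and also without G34R replicate 3 at 10 weeks for Fdft1 (0.0551) and WT replicate 4 at day 7 for Usp18 (0.0523).

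Between day 7 and 10 weeks in WT, 7468 genes rose and 7716 fell of 22425. Myelin genes rose and genes of immature neurons fell. Mobp, a myelin protein gene, rose from 2.03 ± 0.651 CPM (n = 4) to 680 ± 98.8 CPM (n = 6), a log2 fold change of 8.38 (SE 0.399), and Ermn by 6.61 (SE 0.182). All 20 myelin genes rose (20 adjusted over the list alone, median 4.48, camera adjusted p = 0.0311 with an estimated correlation), in list tests added to the planned ones. All 15 immature neuron genes fell (15 adjusted over the list alone, median -3.13, camera adjusted p = 1.72e-05). Pvalb, the marker of fast-spiking interneurons (6.72, SE 0.341), Lamp5 (3.65, SE 0.114), the glycolytic astrocyte gene Aldoc (2.06, SE 0.0569) and the microglial genes Selplg (3.01, SE 0.136) and Tmem119 (2.23, SE 0.11) rose. The neuronal cytoskeletal genes Tubb3 (-2.66, SE 0.0611) and Stmn2 (-2.26, SE 0.0501), Trim67 (-6.29, SE 0.144), the serotonin transporter gene Slc6a4 (-6.22, SE 0.547) and H3f3a (-0.68, SE 0.058) fell. Cholesterol synthesis (16 of 18 lower, p = 0.0558), cell cycle (19 of 20 lower, p = 0.0701), homeostatic microglia (12 of 14 higher, p = 0.0701) and homeostatic astrocytes (15 of 18 higher, p = 0.0899) did not pass with an estimated correlation. Between males alone 13430 genes were called. The labels give no library dates for either age, and age cannot be separated here from batch or from library composition. Protein-coding genes held 73.06% to 78.98% of the counts in WT libraries at 10 weeks and 83.94% to 84.67% at day 7. The calls between ages may therefore come in part from the libraries.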

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

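The tests on chromosome 11 and on microglial genes in this part were chosen after the results were seen, and the counts of other splits were planned. Of 184 groups of values tested for a single outlying animal or library, 15 had one, and chance gives about 1 in 20 groups. The mutant groups at 10 weeks held too few animals for this test and were not examined with it. In WT at 10 weeks, Tlr2 was at 1.5 CPM in replicate 6 (others 0.858 to 1.09) and Ccl3 at 0.229 CPM in replicate 5 (0.0231 to 0.0983). Replicate 1 stood out for Olig1 (60.6 CPM, others 48.4 to 52.8), Enpp6 (11.5, 7.11 to 8.75), Pcdhb9 (16.5, 14.3 to 14.9) and Tmem119 (22.1, 18.8 to 20), and replicate 2 for Trim71 (2.63, 1.46 to 1.85) and Tet1 (20, 17.5 to 18.4). The library of WT replicate 4 held 90.1 M counts (M, mega), against 36.5 to 57.3 M. In G34R at day 7, replicate 2 had 0.516 CPM of Itgax (1.39 to 1.54) and 0.585 of Trim71 (0.205 to 0.241), and replicate 1 had 8.18 CPM of Lamp5 (11.8 to 12.5) and 85.1% of its counts on protein-coding genes (84.2% to 84.3%). In WT at day 7, replicate 1 had 3.65 CPM of Gpr179 (0.649 to 0.805) and 28.4 M counts (44.4 to 47.1 M).

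For 15 named genes the G34R effect differed between 10 weeks and day 7 in edgeR's test of the difference. The effect at 10 weeks minus that at day 7 (log2) was 6.752 for Cst7, 4.579 for Itgax, 4.297 for Clec7a, 2.612 for Usp18, 2.548 for Lyz2, 2.429 for Cxcl16, 1.988 for Gfap, 1.194 for Ggta1 and 0.976 for C1qa. It was -3.224 for Zfp648, -2.412 for Trim71, -0.958 for Lamp5, -0.796 for Ndn, -0.362 for Lss and -0.353 for Fdft1.

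Other splits of the same animals were counted for each comparison of groups of at least 3. For G34R at 10 weeks 1 of 84 splits, the real one, gave as many genes (1190; highest other 98), and for G34V 1 of 84 (905; highest other 198). At day 7 it was 1 of 35 (63, highest other 51), for the difference between ages 1 of 100 (261, 18) and for age in WT 1 of 100 (15184, 9231). The day-7 count lay close to the highest other split and fell to 5 to 39 with 1 animal left out. Some day-7 splits also did not balance sex as the real one does, so the splits alone do not exclude chance assignment there. In the separate 10-week animals 60 of the 61 day-7 calls tested had the same sign, against 53.8% of genes not called at day 7. Of the 61, 31 were also called with that sign and 0 with the opposite one. This argues against chance assignment for these calls as a set, though genes of the same animals are not independent. The counts of the other comparisons lay well above every other split tried. The 10-week splits also mixed library sets and number runs, which the real groups partly follow, so they do not separate genotype from these. The highest other values for age came from splits that put all 4 day-7 animals together in the larger group, a structure of the samples. For G34R against G34V the 10 splits are too few for a share under 0.05 (real split 49, highest other 1).

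Microglial genes rose in G34R at 10 weeks, and 2 other explanations, a larger share of microglia and tissue from outside the cortex, were set against a change of expression within microglia. A larger share of microglia with unchanged expression would raise their genes alike, but 10 of 22 disease-associated genes lay above the top of the homeostatic range by over 2 SE, which argues against it as the whole cause. The medians of the lists, 0.7 and 0.496, differed by an amount that did not pass a permutation test (p = 0.395). Blood or meningeal tissue was a candidate source, but the highest of the medians of its 3 lists was 0.197, below the lower quartile of 0.338 of the homeostatic list. Their abundant genes included Hbb-bs (140 ± 14.4 CPM against 119 ± 35.3 in WT), Ptgds (393 ± 89.2 against 367 ± 96.5) and Trbc2 (6.06 ± 1.11 against 9.68 ± 2.43). Of the lists' genes, 0 of 8, 1 of 14 and 0 of 16 were in another list. Only 7 of the 16 leukocyte genes were tested. Of these, Ccr2 (0.498 ± 0.0646 CPM against 0.355 ± 0.0794), Ms4a7 (0.397 ± 0.115 against 0.261 ± 0.0808) and Ly6c2 (3.09 ± 0.956 against 2.85 ± 0.87) had higher means in G34R, and S100a8, S100a9, Cd4 and Trbc2 lower ones. The list median therefore does not decide on entry of monocytes or macrophages. A change within microglia, with or without a larger number of them, stays open as a hypothesis. Within the library set that the G34R animals share with 3 WT libraries (965 genes called), every microglial gene named for G34R kept its call.

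Calls in G34V were frequent on chromosome 11, with 101 of 905 (11.2%; 8.2% of tested genes; odds ratio 1.43, Fisher's exact p = 0.00157), against odds ratios of 1.06 in G34R and 1.22 in G34W. Among 76 genes that separated G34V from both other substitutions, 16 were on chromosome 11 (odds ratio 3, 95% interval 1.61 to 5.28, Fisher's exact p = 0.000383), which is consistent with a strain variant region carried by the G34V animals. Glial response genes that happen to lie there are argued against by an odds ratio of 1.87 (1.38 to 2.5, Fisher's exact p = 6.15e-05) among the 396 G34V calls not called in G34R. These Fisher's tests take genes as independent, which genes of the same animals are not, so their p and intervals may overstate the evidence. Chromosome 11 was picked for its excess of G34V calls, and p was not corrected for that choice. The 76 genes come from the same G34V animals, so they are no independent test of that excess. Rpl26 was at 42.73, 41.92 and 42.9 CPM in the G34V animals and at 67.22 to 86.44 in the other 10-week animals, and at day 7 at 14.79, 69.02, 46.15 and 42.74 in WT and 64.29, 14.6, 68.13 and 41.14 in G34R, so its level varied between animals within both day-7 genotypes. Krt12 was at 1.39 and 1.43 CPM in day-7 G34R replicates 2 and 4, against 11.42 and 11.16 in replicates 1 and 3. In WT at day 7 it was at 4.71 in replicate 1 and at 8.35 to 9.49 in the others. Animals of the same genotype thus differed in Rpl26 and Krt12, WT included, which argues against the substitution as the sole cause for these 2 genes. Reads that would show variants were not analysed here, so a region linked to strain and an added effect of the substitution stay open.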

How the results depend on the processing

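The 2 alternatives based on library sets were chosen after the data were seen, and the other alternatives were planned. Of 2018 outcomes for named genes under 16 settings, 1854 kept direction and side of the threshold. Another 156 lost their call, 8 gained one and 0 changed sign. The losses were uneven between settings. Number runs as a block ended the call in 48 of 131 outcomes and library sets as a block in 26 of 131. Use of only the set that holds the mutant ended it in 17 of 106, and DESeq2 in 0 of 178. With 1 animal left out 1379 of 1607 outcomes kept direction and side of the threshold and 228 lost their call. Of 337 outcomes for lists 256 kept their call, 78 lost it (59 of these with an estimated correlation) and 3 reversed. The reversals were mitochondrially encoded genes in G34R (camera adjusted p = 0.66 with number runs as a block, 0.926 with library sets as a block) and deep-layer neurons in G34W (0.943 with number runs as a block). The library sets were defined by the share of mitochondrial counts, so that block removes a mitochondrial difference by construction and tests nothing there, and the cause of the others was not tested. An estimated correlation left 8 of 17 lists in G34R, 4 of 15 in G34V, 0 of 18 in G34W, 1 of 11 at day 7 and 7 of 18 for the difference between ages. No filter gave 159 genes and 7 lists at day 7. DESeq2 gave 917 genes for G34W, 281 for G34R against G34V, 1116 for G34R against G34W, 309 for G34V against G34W, 211 at day 7 (104 higher and 107 lower, against 23 and 40) and 460 for the difference between ages. Voom with quality weights gave 28, 201, 86 and 9 for the same first 4, and 117 at day 7. Only the compared groups gave 140 for G34W and 169 for G34R against G34V. Number runs as a block gave 751 for G34R, 340 for G34V, 15 for G34W, 3 for G34R against G34V, 6 for G34R against G34W and 4 for G34V against G34W. The sex label as a covariate gave 630 for G34W (186 of them among the 347) and 307 for G34V against G34W. Library sets as a block gave 126 for G34W, 11, 35 and 76 between the substitutions in the same order, and use of only the set that holds the mutant gave 519 for G34V and 91 for G34W, from fewer samples. Shared calls went from 506 to 822 (G34R and G34V), 139 to 402 (G34R and G34W) and 168 to 482 (G34V and G34W) at an unadjusted p under 0.01, and to 293.5, 65.3 and 76.7 with separate sets of 3 WT animals. The cause of the other moves was not tested. With 1 animal left out, the counts were 692 to 1093 for G34R (692, 758 and 755 without G34R replicates 1, 2 and 3), 497 to 856 for G34V (497 and 513 without G34V replicates 1 and 2), 58 to 590 for G34W (58 and 590 without G34W replicates 1 and 2, 219 without WT replicate 1) and 14382 to 15007 for age. They were 13 to 129 for G34R against G34V (16, 22 and 25 without G34R replicates 1, 2 and 3, and 13, 18 and 129 without those of G34V), 149 to 508 for G34R against G34W (159, 149 and 164 without G34R replicates 1, 2 and 3, and 212 without G34W replicate 1) and 10 to 301 for G34V against G34W (10 without G34V replicate 1 or 2, 301 without G34W replicate 2). At day 7 they were 5 to 39 (31, 19, 39 and 7 without G34R replicates 1 to 4, and 7, 28, 39 and 5 without those of WT), and for the difference between ages 133 to 281 (133 and 172 without 10-week G34R replicates 1 and 2). The number of lists ranged from 15 to 20 in G34R, 15 to 19 in G34V, 16 to 21 in G34W, 8 to 14 at day 7 and 13 to 20 for the difference. A G34W group of 1 animal was assumed to vary like the other groups. The 2 libraries of WT replicate 3 differed by more than counting noise, with a chi-square per degree of freedom of 19.6. The second of them was nearer to WT replicates 5 and 6 of its library set (12 and 11.6; 7.24 between these 2 animals) but not to WT replicate 2 of that set (49.7), and the first was nearer to the second than to any other WT library (21.9 to 40.3).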

Other observations

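The tests of genes near H3f3a and of the persistence of day-7 differences were chosen after results were seen, and those of gene length and developmental direction were planned.

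Of 26 tested genes within 1 Mb of the start of H3f3a, 4 were called in at least 1 substitution, against 8.2% of other genes (odds ratio 2.04, 95% interval 0.511 to 6.02, Fisher's exact p = 0.159). They were Gm5069, Tmem63a and the near copies Lefty1 and Lefty2. A local effect of the edited allele may raise the number of calls there, but the interval includes both 1 and values well above 2, so these data do not decide it. The test also takes the genes as independent, which genes of the same animals are not.

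Genomic length was not related to the G34R effect in the direction of higher expression of long genes, with a Spearman's rho of -0.069 across 20867 genes (-0.063 in G34V and -0.104 in G34W). Genes are not independent replicates, so no p is given.

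Whether G34R moved the 10-week cortex towards the expression of day 7 was tested with separate WT animals for the 2 changes. Spearman's rho across 22425 genes was 0.033 and -0.008 in the 2 planned assignments of the WT animals and ranged from -0.047 to 0.062 over all 20 assignments, which argues against a general shift of that kind.

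Of 61 genes called in G34R at day 7 and tested at 10 weeks, 60 (98.4%, 95% interval 91.2% to 100%) had the same sign at 10 weeks and 31 were also called with that sign, with 0 called in the opposite direction, whereas 53.8% of 19799 genes not called at day 7 had the same sign at both ages. The interval takes the 61 genes as independent, which genes measured in the same animals are not, so it may be too narrow. All 40 genes lower at day 7 were lower at 10 weeks. Animals of the 2 ages were separate, so this is consistent with day-7 differences that last to 10 weeks. Phyh was at -0.99 and -1.21 at the 2 ages. Pi15 was at 1.79 at day 7 and did not pass at 10 weeks (0.87, edgeR adjusted p = 0.214). In G34V 57 of the 61 had the same sign (31 called) and in G34W 50 (10 called).

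Among genes that G34R and G34V shared, 158 of 196 higher ones rose more in G34R, and 146 of 310 lower ones fell more in G34R. In G34W, Minar2 (-1.22, SE 0.103) and Hrasls (-1.27, SE 0.182) fell, each with a call that held with any 1 animal left out. Among chromatin regulators, Tet1 (-0.27 in G34R and in G34V) and Kdm2b (0.24 and 0.29) passed in both, but left out 1 at a time, the animals ended the call of Tet1 in 8 of 9 and 9 of 9 cases and that of Kdm2b in 7 of 9 and 1 of 9 (G34V replicate 1, edgeR adjusted p = 0.11).

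AA465934 on chromosome 11 was at 7.45, 7.12 and 6.27 CPM in the G34V animals and at 0.46 to 1.3 in the other 10-week animals. At day 7 it was at 6.1, 0.86, 1.18 and 6.74 CPM in WT replicates 1 to 4 and at 1.33, 12.09, 2.17 and 10.98 in G34R replicates 1 to 4. Gpr179 was at 3.65, 0.8, 0.65 and 0.71 CPM in these WT animals and at 0.87, 7.02, 1.15 and 17.27 in these G34R animals.

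The signal recognition particle RNA genes Rn7s1 and Rn7s2, which are near-identical copies and cannot be told apart with certainty, were at 4041 ± 896 and 113300 ± 15740 CPM in WT at 10 weeks (n = 6) and at 55490 ± 3928 and 3983 ± 373.8 CPM in WT at day 7 (n = 4).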
